A study of Mus musculus with 28 samples.

How the data were processed

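RNA was measured in macrophages sorted from atherosclerotic plaques of Apoe-deficient mice, in 22 libraries from 2 experiments. The first compared VCAM1 positive with VCAM1 negative plaque macrophages (6 libraries each). The second compared total plaque macrophages of mice given siRNA against Cmpk2 (5 libraries) or a control siRNA (5 libraries). Another 6 samples of the series are spatial transcriptomes of aortic roots and were not analysed here. Groups and replicate numbers were taken from the sample labels.

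For each experiment the authors deposited a separate table, with RPKM values (reads per kilobase of exon and per M, or mega, reads) for 41819 genes and 1 column per library, per the file headers. RNA was extracted with a kit for small cell numbers and libraries were made by standard Illumina protocols, per the labels' protocols. The submitters' processing notes name the mm10 genome build, Partek 10.0.22.1204 and Seurat without saying what each was used for. The mapper, the counting rule and the use of strand are not given in the sources used here, so reads shared by overlapping or antisense genes, or by near-identical family members such as Ly6c1 and Ly6c2 or the Cd209 genes, could have been divided in ways these values do not show. Every one of the 41819 genes matched the coordinates of a gene in the GENCODE M21 annotation of the same build, which supplied identifiers, positions and exon lengths.

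RPKM holds no read counts, but the low values still show what 1 read was worth. In the 21368 genes with a single annotated transcript, the values of each library were whole multiples of the value of 1 read, within a tolerance of 0.01, for 100% of the values checked. That gave the total used to scale of each library, called its reads here: 22.3 to 42.3 M in the VCAM1 experiment and 0.0365 to 43.9 M in the siRNA experiment, a 1201-fold range. A single read in a 1 kb transcript was worth an RPKM of 0.0236 to 0.0449 in the VCAM1 experiment. In the siRNA experiment it was worth 27.4 in siCmpk2 library 4 and 0.0228 to 0.869 in the others. The sum of RPKM times exon length gave an upper estimate of the share of reads on exons. Levels given for 3 reads cover counting error only, because the reads carry no molecular identifiers that are used here. No 2 libraries of a group were alike within sampling noise: a chi-square of their recovered reads divided by its degrees of freedom was at least 13.8, over genes with at least 20 reads.

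Each experiment was fitted alone, since the tables were made separately and share no library. A count test had been planned for a table of counts, with limma as the planned test for normalized values. The unit decided for limma. Genes were kept with an RPKM of at least 1 in at least as many libraries as the smaller group held (6 and 5), which left 10492 and 6315 genes. The values were log2(RPKM + 1), and limma 3.58.1 (R 4.3.3, statmod 1.5.0, and the data.table package, version 1.17.8) was run with a mean-variance trend and robust moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. RPKM was not rescaled between libraries in these fits.

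The groups, tests, 34 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took 10 genes always given (Vcam1, Cmpk2, Itga4, Nlrp3, Il1b, Tmem173, Cgas, Irf1, Adgre1 and Cd68). It added the 6 called genes with the largest and the 6 with the smallest log2 fold change among named genes above the median expression of the tested genes, filled with the smallest p where fewer were called. From each list with called members it took the 3 or fewer with the smallest p. In lists with none, up to 2 members could be given as values.

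The lists cover macrophage states (resident-like, monocyte and recently recruited, lipid-laden, iron recycling, efferocytosis and complement), inflammation (type I interferon, interferon gamma and guanylate binding proteins, inflammasome and interleukin 1, DNA sensing, NF-kB cytokines and chemokines, MHC class II presentation), metabolism (pyrimidine synthesis, mitochondrial DNA maintenance, mitochondrially encoded proteins, nuclear oxidative phosphorylation, glycolysis, LXR targets, cholesterol biosynthesis), integrins and adhesion, extracellular proteases, cell cycle and dissociation stress. Marker lists cover dendritic, smooth muscle, endothelial, T, B, NK, mast and erythroid cells, fibroblasts, neutrophils, platelets and adipocytes. Vcam1 and Cmpk2 were kept out of the lists. Lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01, which ranks a list's genes against all other tested genes. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance.

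The headers of the VCAM1 table name the same 6 aortas in both sorted populations. Deviations from the group means correlated between the libraries of one aorta at 0.359, 0.229, 0.603, 0.369, 0.228 and 0.418 over the tested genes. For aortas 2 and 5 another number correlated higher, at 0.256 and 0.345, and the numbers were taken to pair the libraries on the headers. The fit reported has no block, as planned, and a fit with the aorta as a block was run beside it. In the siRNA experiment the numbers belong to different animals.

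The alternatives were quantile normalization, centring on library medians, array weights, no low-value filter, a mean RPKM of at least 5, a pseudocount of 0.1, an adjusted p under 0.01, an added log2 fold change of at least 1, the replicate block, and leaving out each library. Chosen after seeing the data were equal RPKM sums, centring with the block, fits of aortas 1 to 3 and of aortas 4 to 6, a fit without the negative libraries of aortas 4 to 6, siRNA fits without siCmpk2 library 4 and centred, and siRNA fits on libraries with more than 4 M reads. For each comparison 100 divisions of the libraries into groups of the same size, the real one included, were fitted, and all 32 divisions that part the 6 aortas were refitted with the block. Single values were compared by exact two-sided permutation tests.

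The fits were tested on simulated data built from each experiment's own gene means and residual spread, in 5 runs of each. For the VCAM1 comparison (10492 genes), 69.4% of genes changed by 1 log2 unit and 93.6% of those changed by 2 were called. For the siRNA comparison (6315 genes) 0 of 500 were called at either size. The median residual SD per gene was 0.337 log2 units in the VCAM1 experiment and 1.35 in the siRNA experiment. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.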

Results

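Plaque macrophages were collected from Apoe-deficient mice, which develop atherosclerosis, after 4 months of an atherogenic diet. In the first experiment, macrophages were sorted by the surface adhesion molecule VCAM-1 into positive and negative populations, with 6 libraries of each from 6 aortas. In the second, mice received siRNA against Cmpk2, which encodes a mitochondrial nucleotide kinase, or a control siRNA, carried by lipidoid nanoparticles for 1 month, and total plaque macrophages were taken (5 libraries of each). The libraries of one group came from separate aortas by their labels. Expression was given as RPKM.

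Depth was even in the first experiment and uneven in the second. The sorted libraries held 22.3 to 42.3 M (mega) reads, with 14345 to 17706 genes above 0. The siRNA libraries ran from 36530 reads and 236 genes above 0 in siCmpk2 library 4 to 43.9 M reads and 16969 genes in siControl library 3. The other siCmpk2 libraries held 11.5, 4.58, 10.7 and 1.34 M reads, and the other siControl libraries 1.54, 1.19, 1.15 and 4.25 M. At most 30.2% to 59.5% of the reads lay on exons in VCAM1 negative libraries, 49.4% to 67.7% in VCAM1 positive, 16.8% to 71.4% in siCmpk2 and 23.6% to 43.1% in siControl.

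**Figure D1:**
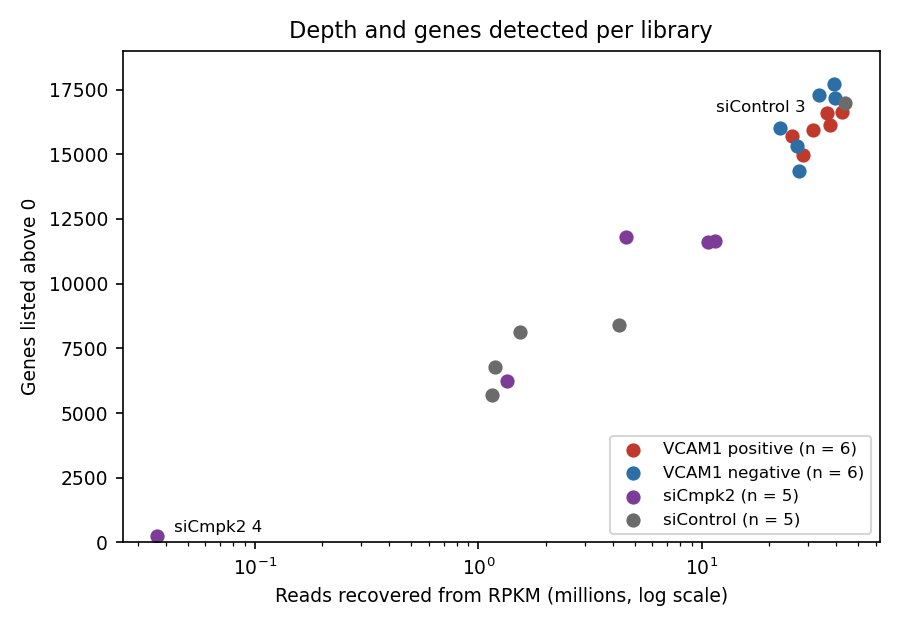
Reads recovered from the RPKM values (M, log axis) against the number of genes listed above 0, with 1 point per library and colours for the 4 groups. The 12 sorted libraries sit between 22.3 and 42.3 M reads, while siCmpk2 library 4 holds 236 genes and siControl library 3 holds 16969.

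The first comparison asked how VCAM1 positive plaque macrophages differ from VCAM1 negative ones. Positive libraries had higher levels of the sorting marker, of 17 of 21 genes of resident-like macrophages, of 8 of 21 genes of the uptake of dying cells, and of Cytl1, Clu, Selp, Smoc1 and Vwf. Lower were 8 of 11 T cell markers and 5 of 21 monocyte genes. These 4 lists were called only at the preset correlation (adjusted p = 0.6251, 0.771, 0.244 and 0.35 with an estimated correlation), and 3 negative libraries were low in general macrophage genes. The endothelial gene Cdh5 and the smooth muscle gene Myh11 were listed in every sorted library, at 12.4 to 133.4 and 18.4 to 262.1 RPKM. Vcam1 itself (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688 of mm10, minus strand) measured 33.3 ± 14.1 RPKM in positive and 5.26 ± 2.24 in negative libraries (SD, n = 6 each). Its log2 fold change was 2.44 (SE 0.38, limma adjusted p = 0.00434), it was higher in 6 of 6 aortas, and an exact permutation test of the 924 divisions gave p = 0.00216.

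**Figure D2:**
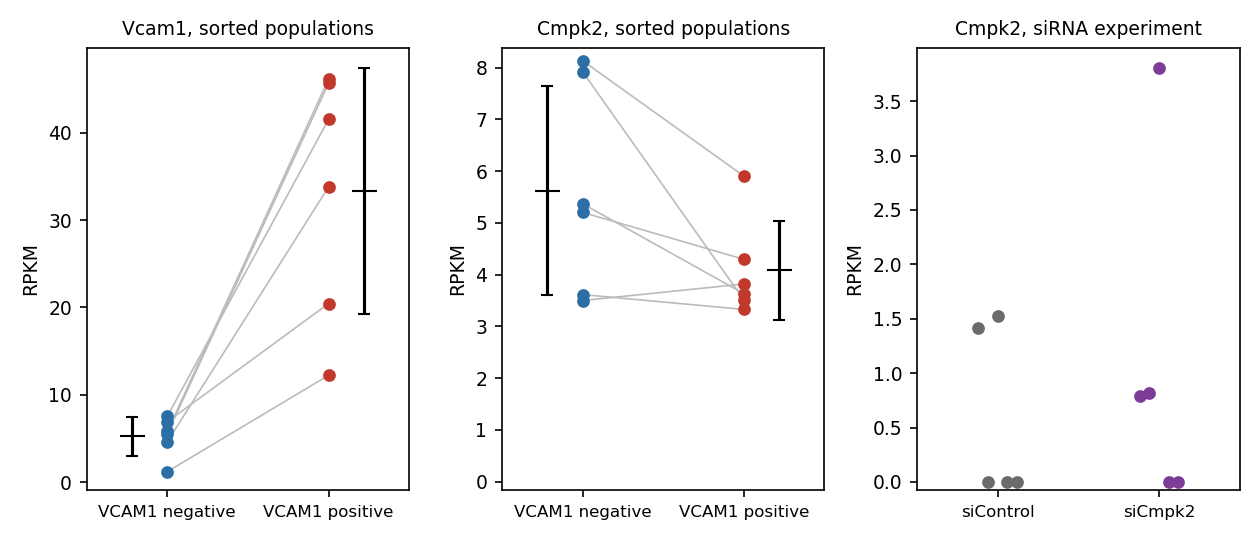
RPKM of Vcam1 and Cmpk2 in the sorted populations (6 aortas, grey lines join the libraries of one aorta, bars show mean ± SD) and of Cmpk2 in the siRNA experiment (5 libraries per group). Vcam1 lies higher in the positive library of each aorta, Cmpk2 lies lower in 5 of 6, and 2 siCmpk2 and 3 siControl libraries list Cmpk2 at 0.

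Resident-like macrophage genes rose together in number: 17 of 21 tested members were called higher and 0 lower (21 higher adjusted over the list alone), with a median log2 fold change of 1.78. Among them were Gas6, a bridging ligand in the clearance of dying cells (1.67, SE 0.35, adjusted p = 0.0135), and the scavenger receptor Stab1 (1.78, SE 0.39, adjusted p = 0.0155). The mannose receptor Mrc1 measured 108.9 ± 20.4 RPKM in positive and 32.6 ± 33.4 in negative libraries (log2 2.93, adjusted p = 0.0422), and the chemokine Ccl8 91.8 ± 39.4 and 20.4 ± 21.5 (log2 3.28, adjusted p = 0.0309). Cd209g, of a family of near-identical lectins, was also called (1.51, adjusted p = 0.0118). In aortas 1 to 3 alone 0 members were called without the aorta as a block and 16 with it, all higher, and 1 was called without the negative libraries of aortas 4 to 6. The list as a whole ranked above other genes with camera (adjusted p = 2.75e-07), and adjusted p = 0.6251 with an estimated correlation. When each library was centred on its median, 6 members were called and the calls of Mrc1 (2.63, adjusted p = 0.0787) and Ccl8 (2.98, adjusted p = 0.0577) ended at similar fold changes. Efferocytosis and complement genes went the same way, with 8 of 21 called higher (16 adjusted over the list alone, camera adjusted p = 0.000814, adjusted p = 0.771 with an estimated correlation). They included the phagocytic bridge Mfge8 (1.36, adjusted p = 0.0121), and Gas6 and Stab1 stand in both lists.

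These groups moved with the macrophage content of 3 negative libraries. In the negative libraries of aortas 4, 5 and 6, Cd68, a macrophage lysosomal protein, measured 1.95, 9.54 and 18.2 RPKM, against 38.1 to 74.0 in the negative libraries of aortas 1 to 3 and 37.1 to 72.6 in the positive libraries. Complement C1qa measured 5.13, 7.90 and 19.3 there against 173 to 223 in aortas 1 to 3. The neutrophil genes S100a8 and S100a9 went the other way, with S100a8 at 342.9, 451.2 and 512.3 in those libraries against 5.65 to 34.6 in the negative libraries of aortas 1 to 3. The positive-minus-negative difference itself differed between the 2 sets of aortas for 491 of 10492 genes (limma interaction, adjusted p under 0.05), 310 of them larger in aortas 4 to 6. The median of the resident-like list was 0.79 in aortas 1 to 3 and 2.70 in aortas 4 to 6, with camera adjusted p = 1.72e-25 for the difference and adjusted p = 0.0684 with an estimated correlation. The efferocytosis and complement list also rose more in aortas 4 to 6 (camera adjusted p = 4.11e-11, and 0.363 with an estimated correlation).

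Monocyte and recently recruited macrophage genes were lower as a list (camera adjusted p = 8.53e-09, adjusted p = 0.35 with an estimated correlation). Of 21 tested, 5 were called lower and 1 higher (6 and 2 adjusted over the list alone). Lower calls were 0 in aortas 1 to 3 (10 with the block), 5 in aortas 4 to 6 and 2 without the negative libraries of aortas 4 to 6. Ly6c2 and Chil3 were not called in aortas 1 to 3, at −2.039 and −1.685 (adjusted p = 0.353 and 0.314). Nor were they without those libraries, at −1.831 and −1.203 (adjusted p = 0.276 and 0.408). Ly6c2, a marker of inflammatory monocytes with a near-identical copy in Ly6c1, fell from 36.4 ± 31.1 to 3.94 ± 4.82 RPKM (log2 −2.79, SE 0.72, adjusted p = 0.0263). Chil3, a lectin of alternatively activated and recruited cells, fell from 75.4 ± 66.9 to 7.43 ± 5.73 (log2 −2.74, adjusted p = 0.0376). Its call ended after centring at a larger fold change (−3.04, adjusted p = 0.0529). Itgal, the alpha chain of the leukocyte integrin LFA-1, fell by 1.74 (SE 0.35, adjusted p = 0.0121). The member that rose was Ace, angiotensin-converting enzyme (1.68, adjusted p = 0.0182).

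T cell markers were lower, with 8 of 11 tested called (9 adjusted over the list alone), 0 higher and a median of −1.72. The calls were 1 in aortas 1 to 3 (8 with the block, median −0.88), 11 in aortas 4 to 6 (median −2.31) and 1 without the negative libraries of aortas 4 to 6 (median −1.10), with adjusted p = 1.01e-08 for the difference between the sets and adjusted p = 0.363 with an estimated correlation. Lat, an adaptor of T cell receptor signalling, fell from 8.01 ± 6.86 to 0.731 ± 0.638 RPKM, Cd8b1 from 6.26 ± 7.22 to 0.251 ± 0.202, and Cd3d from 2.79 ± 2.14 to 0.351 ± 0.435 (adjusted p = 0.0121, 0.0123 and 0.0187). For the list, camera gave adjusted p = 1.02e-19, and adjusted p = 0.244 with an estimated correlation. Of 15 neutrophil markers 1 was called lower, Retnlg (log2 −1.92, adjusted p = 0.0431, and −2.22, adjusted p = 0.052, after centring), and 0 adjusted over the list alone. The neutrophil list ranked below other genes (camera adjusted p = 7.48e-11, adjusted p = 0.34 with an estimated correlation), and was no longer called without the negative libraries of aortas 4 to 6 (adjusted p = 0.132), where its median turned from −1.67 to 0.10. That fit keeps the positive libraries of aortas 4 to 6. Within aortas 1 to 3 the list's mean lay at −0.968, −0.409 and −0.596 relative to all tested genes. B cell markers (6 tested) and erythroid markers (6 tested) ranked low with no member called (adjusted p = 0.000104 and 2.57e-06, both adjusted p = 0.34 with an estimated correlation). NK, mast cell, platelet and adipocyte lists had 1, 3, 2 and 1 tested members and were not tested as lists. The platelet member called was Itgb3, an integrin beta chain that macrophages also carry (0.645, adjusted p = 0.0453, not called after centring).

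A group of 5 genes with large rises, put together after their values were seen, is also known from cells of the vessel wall. Cytl1, a small secreted cytokine-like protein, measured 119.7 ± 112.8 RPKM in positive and 6.013 ± 4.202 in negative libraries (log2 3.91, SE 0.63, adjusted p = 0.00555). Clu, the secreted chaperone clusterin, rose by 3.15 (SE 0.40, adjusted p = 0.00185). Selp, the endothelial and platelet adhesion receptor P-selectin, rose by 3.06 (SE 0.49, adjusted p = 0.00554), Smoc1, a matrix protein, by 2.95 (SE 0.29, adjusted p = 0.000508), and Vwf, von Willebrand factor of endothelial cells, by 2.75 (SE 0.53, adjusted p = 0.0112). All 5 were higher in 6 of 6 aortas. Vwf was the 1 endothelial marker called among 16 tested (1 adjusted over the list alone), and the list's median was 0.37 (camera adjusted p = 0.107). Smooth muscle markers had 3 of 15 called higher (4 adjusted over the list alone, camera adjusted p = 0.781): Actg2 (1.55, adjusted p = 0.00925), Cnn1 (1.57, adjusted p = 0.0423) and Acta2 (1.94, adjusted p = 0.048), the last 2 not called after centring. Their median was −0.41 in aortas 1 to 3 and 2.01 in aortas 4 to 6, and that of the endothelial markers 1.25 and −0.51. Fibroblast markers had 0 of 15 called (median 0.88, adjusted p = 0.598). Among genes that fell were Btnl9, a butyrophilin-like membrane protein (−2.16, SE 0.53, adjusted p = 0.0223), and Rgcc, a regulator of the cell cycle (−1.96, SE 0.34, adjusted p = 0.00662). In negative libraries 1 to 6 Btnl9 was listed at 18.1, 18.5, 1.95, 23.3, 9.92 and 11.7 RPKM. The endothelial gene Cdh5 was listed there at 91.9, 85.0, 12.4, 68.7, 39.6 and 36.8. Which cells carried Btnl9 and Rgcc was not tested.

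**Figure D3:**
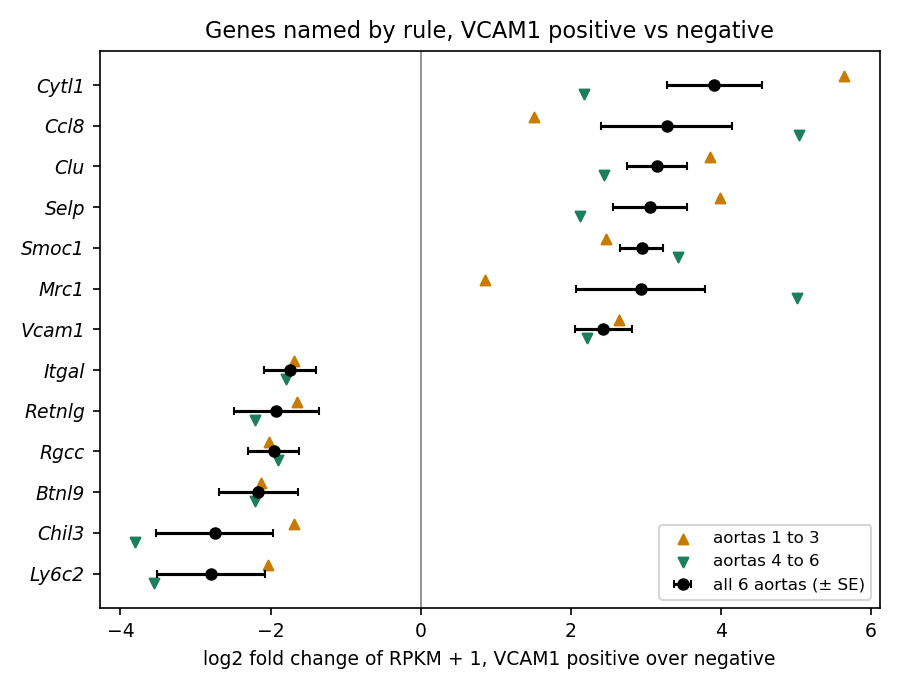
Log2 fold change of RPKM + 1, VCAM1 positive over negative, for Vcam1 and the 12 genes named by rule, with black points for 6 aortas (bars are SE) and triangles for aortas 1 to 3 and aortas 4 to 6. Cytl1 has the largest fold change at 3.91, while Mrc1 moves from 0.85 in aortas 1 to 3 to 5.01 in aortas 4 to 6.

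Integrins and adhesion genes split, with 3 of 26 called higher and 3 lower (5 and 3 adjusted over the list alone). Itga9 (1.57, adjusted p = 0.0112), Itgb1 and Icam1 rose, and Itgal, Itgb7 (−1.73, adjusted p = 0.0166) and Sell fell. The list ranked below other genes (camera adjusted p = 0.0205, adjusted p = 0.81 with an estimated correlation) although its median of 0.39 lay above 0. The same difference in sign held for interferon gamma and guanylate binding genes, which ranked low (adjusted p = 0.00115, adjusted p = 0.726 with an estimated correlation) at a median of 0.08, with Iigp1, an interferon-inducible GTPase, higher (0.73, adjusted p = 0.0223, not after centring) as the only call among 24 (1 adjusted over the list alone). Cell cycle genes (20 tested, median −0.33, adjusted p = 1.58e-10), mitochondrially encoded genes (13 tested, median −0.52, adjusted p = 6.71e-08) and dendritic cell markers (12 tested, median −0.11, mean 0.02, adjusted p = 0.013) ranked low with no member called, at adjusted p = 0.421, 0.443 and 0.421 with an estimated correlation. The cell cycle median was −0.02 in aortas 1 to 3 and −0.69 in aortas 4 to 6, and without the negative libraries of aortas 4 to 6 it turned to 0.23 and the call ended (adjusted p = 0.762). That fit keeps the positive libraries of aortas 4 to 6, so differences between the sets enter it. The median of the mitochondrially encoded genes was −0.92 in aortas 1 to 3 and −0.12 in aortas 4 to 6. All genes of the mitochondrial chromosome took 10.9%, 6.43% and 5.13% of the summed RPKM times exon length in negative libraries 1, 2 and 4. In the other sorted libraries they took 1.43% to 2.74%. With the block, 3 cell cycle genes were called lower, 3 dendritic markers higher and 1 lower. In all, camera called 12 of 30 lists at the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.244) and 0 were called by fry (lowest adjusted p = 0.0804). Other divisions of the same libraries called up to 20 lists at the preset correlation.

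The remaining lists did not pass camera, with adjusted p of 0.182 for DNA sensing and glycolysis, 0.214 for iron recycling, 0.476 for NF-kB, type I interferon and dissociation stress, 0.646 for lipid-laden, 0.727 for oxidative phosphorylation, 0.728 for pyrimidine synthesis, 0.733 for inflammasome, 0.781 for proteases, 0.837 for mitochondrial DNA maintenance and cholesterol biosynthesis, 0.953 for LXR and 0.976 for MHC class II genes. Several ranked below other genes with a median above 0: DNA sensing, glycolysis, type I interferon, dissociation stress, lipid-laden (0.69), pyrimidine, inflammasome, mitochondrial DNA maintenance, cholesterol biosynthesis, MHC class II (1.29) and the endothelial markers. MHC class II genes ranked low in aortas 1 to 3 (median 0.13, adjusted p = 0.00621) and high in aortas 4 to 6 (median 1.77, adjusted p = 0.0143), with adjusted p = 5.64e-12 for the difference and adjusted p = 0.363 with an estimated correlation. Type I interferon genes ranked low in aortas 1 to 3 (median 0.02, adjusted p = 0.000358) and in aortas 4 to 6 were called high only with the aorta as a block (median 0.68, adjusted p = 0.0101 with it and 0.0863 without), with adjusted p = 9.54e-08 for the difference and adjusted p = 0.363 with an estimated correlation. Iron recycling genes ranked high in aortas 4 to 6 (adjusted p = 0.00391), as did NF-kB genes with the block (0.00381), against 0.897 for each in aortas 1 to 3 without the block. The difference between the sets had adjusted p = 8.46e-06 and 0.000105, and adjusted p = 0.478 and 0.604 with an estimated correlation. NF-kB cytokines and chemokines had 3 of 25 called higher: the chemokine Ccl12 (2.25, adjusted p = 0.028), the adhesion molecule Icam1 (1.28, adjusted p = 0.0409) and the cytokine Il10 (0.88, adjusted p = 0.0423). Extracellular proteases and inhibitors had 4 of 18, led by the inhibitor Timp3 (1.28, adjusted p = 0.0179), with the proteases Plau (0.95) and Adam9 (1.25). Lipid-laden macrophage genes had 2 of 21, the tetraspanins Cd9 (1.35, adjusted p = 0.0201) and Cd63 (1.14). LXR targets had 2 of 17, the cholesterol hydroxylase Ch25h (1.04, adjusted p = 0.00701) and the transfer protein Pltp (1.73). Pyrimidine synthesis had 2 of 21, the CTP synthase Ctps (1.30, adjusted p = 0.0121) and the ribonucleotide reductase subunit Rrm2b (0.46). DNA sensing had 2 of 22, Xrcc5 (0.56) and Dnase2a (0.93). Single calls, all higher, were the ATP receptor P2rx7 among 18 inflammasome genes (1.13, adjusted p = 0.0306), Pfkm among 18 glycolysis genes (0.64, adjusted p = 0.0131), Blvrb among 16 iron recycling genes (0.91, adjusted p = 0.0473) and the costimulatory molecule Cd86 among 13 MHC class II presentation genes (1.29, adjusted p = 0.0429). Adjusted over the list alone, the counts were 3, 8 (and 1 lower), 2, 4, 2, 2, 1, 1, 5 and 0 in that order. Type I interferon (34 tested), mitochondrial DNA maintenance (16), nuclear oxidative phosphorylation (40), cholesterol biosynthesis (15) and dissociation stress genes (26) had 0 calls without the block and 9, 2, 10, 2 and 3 higher with it (and 1 dissociation stress gene lower). Adjusted over the list alone they had 0, with medians of 0.33, 0.20, 0.35, 0.27 and 0.42. Of the genes named in these lists, Timp3, Cd9, Ch25h and Ctps kept their calls after centring and the others did not. The others kept their direction, at log2 fold changes from 0.16 for Rrm2b to 1.95 for Ccl12 after centring.

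Cmpk2 (ENSMUSG00000020638, chromosome 12, 26469204 to 26479837, plus strand) measured 4.08 ± 0.952 RPKM in positive and 5.62 ± 2.02 in negative libraries (SD, n = 6). Its log2 fold change of −0.34 (SE 0.20) did not pass limma's threshold (adjusted p = 0.214), and it was lower in 5 of 6 aortas. It passed after quantile normalization (−0.64, adjusted p = 0.0353), centring (−0.64, adjusted p = 0.0403) and scaling to equal RPKM sums (−0.51, adjusted p = 0.0366). Of the other genes always given, the macrophage genes Adgre1 (1.86, adjusted p = 0.0732) and Cd68 (1.501, adjusted p = 0.1045) and the DNA sensing adaptor Tmem173 (0.58, adjusted p = 0.146) were called in the fit with the aorta as a block (adjusted p = 0.0359, 0.0363 and 0.0308). The inflammasome gene Nlrp3 (0.78, adjusted p = 0.322), the VCAM-1 ligand chain Itga4 (−0.36, adjusted p = 0.429), Il1b (0.18, adjusted p = 0.87), Irf1 (0.10, adjusted p = 0.717) and Cgas (log2 difference −0.0027, adjusted p = 0.993) were not called.

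Of 10492 genes tested, limma called 1408, 1326 higher and 82 lower, at adjusted p under 0.05. The upper estimate of the share of reads on exons was also higher in the positive library of each aorta, with 49.4% against 30.2% in aorta 4. Its part in these calls was not tested on its own. Scaling to equal RPKM sums left 988 calls, 924 higher and 64 lower. The median of all tested genes was itself 0.29 above 0, and after centring on library medians 551 genes were called, 346 higher and 205 lower. With the aorta as a block 3629 were called (3351 higher), and with the block and centring together 1526, 741 higher and 785 lower. Aortas 1 to 3 gave 102 without the block and 970 with it, aortas 4 to 6 gave 1433 and 3733, and the fit without the negative libraries of aortas 4 to 6 gave 132. Leaving out single libraries gave 3004 calls without negative library 3, and 573, 735, 565, 644, 567 and 558 without negative library 5 and positive libraries 1, 2, 3, 5 and 6. The 47 named genes that were called had the same sign in every alternative run, and 24 stayed called whichever library was left out. These were Vcam1, Cytl1, Clu, Selp, Smoc1, Vwf, Rgcc, Itgal, Ace, Lat, Cd8b1, Cd3d, Cd209g, Gas6, Stab1, Mfge8, Itga9, Itgb7, Timp3, Ch25h, Cd9, Ctps, Pfkm and Actg2. In aortas 1 to 3 alone, without the block, 10 of the 47 were called (Vcam1, Cytl1, Clu, Selp, Smoc1, Vwf, Ace, Cd8b1, Cd9 and Ctps).

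**Figure D4:**
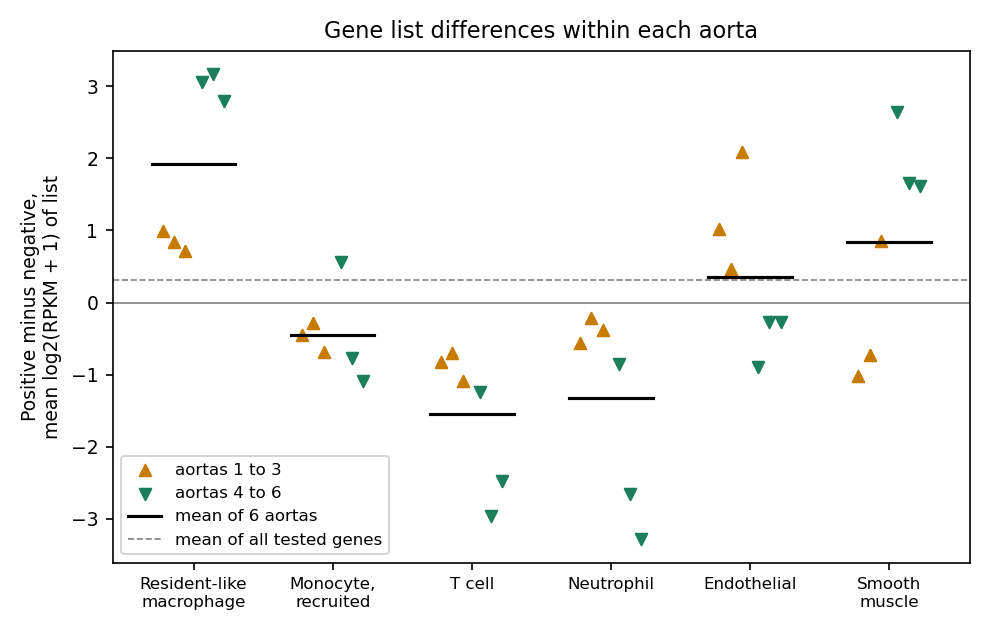
Positive minus negative difference in the mean log2(RPKM + 1) of 6 gene lists, with 1 symbol per aorta, a bar for the mean of 6 aortas and a dashed line for the mean of all tested genes. The resident-like list lies above 0 in 6 of 6 aortas, from 0.72 to 3.17, and the T cell list below 0 in 6 of 6.

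The second comparison asked what siRNA against Cmpk2 changed in total plaque macrophages. No lowering of Cmpk2 itself was measured. The libraries labelled siCmpk2 listed it at 0.791, 0.819, 3.80, 0 and 0 RPKM, and those labelled siControl at 1.42, 0, 1.52, 0 and 0, and the highest value was in the library labelled siCmpk2 3. The difference of siCmpk2 minus siControl was 0.27 on the log2 scale, with an exact permutation p = 0.683 over 252 divisions (the smallest possible is 0.00794). Without a low-value filter limma gave a 95% interval of −0.87 to 1.41 (adjusted p = 0.961), and a value of 0 in all 5 siCmpk2 libraries would have given −0.52, which lies inside that interval, so a lowering was neither shown nor excluded. The difference was −0.02 after centring and −0.10 without siCmpk2 library 3. A level of 3 reads on Cmpk2 corresponds to 0.0164 to 0.626 RPKM in 9 of the libraries and to 19.7 in siCmpk2 library 4. Directions in this comparison are given by label, since the target did not check the labels.

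No gene passed the test between the libraries labelled siCmpk2 and siControl. limma called 0 of 6315 genes and 140 had an unadjusted p under 0.05. Array weights called 103 genes, all higher, and leaving out siCmpk2 library 4 called 21, all higher, or 0 when the libraries were also centred. Leaving out siCmpk2 library 1 or 2 called 1 gene, 2300009A05Rik, listed at 4050 RPKM in siCmpk2 library 4, and the libraries above 4 M reads called 1, the resistin-like gene Retnla (5.13, adjusted p = 0.00151), both chosen after their values were seen. The smallest p among well-expressed genes belonged, for higher values, to S100a6, Psmd6, S100a11, Uqcr10, Rbck1 and Inpp5k, with log2 differences of 2.92, 2.91, 2.94, 3.09, 3.17 and 2.62 (adjusted p = 1 each). Rbck1 and Inpp5k were listed at 689.8 and 406.9 RPKM in siCmpk2 library 4, where 1 read in a 1 kb transcript was worth 27.4. The other siCmpk2 libraries listed them at 5.25 to 40.2 and 0 to 7.58. The calcium-binding S100a6 was listed at 18.5, 26.6, 17.9, 0 and 37.3 RPKM in the siCmpk2 libraries and 0.513, 0, 9.56, 0 and 0 in the siControl libraries. The respiratory chain gene Uqcr10 was listed at 47.3, 39.7, 31.04, 0 and 111.9, and at 0, 0, 13.7, 0 and 9.76. For lower values they were Pttg1, Parp3, Med8, Stat2, Cep83 and Rapgef2, with log2 differences of −1.75, −1.61, −1.62, −1.54, −1.59 and −1.48 (adjusted p = 1 each). Values of the genes always given were 0.79 for Vcam1, 0.41 for Itga4, −0.35 for Nlrp3, −0.84 for Il1b, 0.30 for Tmem173, 0.18 for Cgas, 0.36 for Irf1, −0.48 for Adgre1 and −0.24 for Cd68 (adjusted p = 1 each). siCmpk2 library 4 lists each of these 9 at 0.

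Of 25 lists tested in the siRNA experiment, camera called 6 at the preset correlation and 0 with an estimated correlation (adjusted p = 0.985 for each), and fry called 0. No member of these 25 lists was called, over all genes or adjusted over the list alone. Nuclear oxidative phosphorylation genes ranked higher in siCmpk2 libraries (39 tested, median 0.60, adjusted p = 0.0216), with Ndufb3 and Ndufb5 at 2.25 and 1.44. Ranked lower were NF-kB cytokines and chemokines (25 tested, median −0.53, adjusted p = 0.0065, with Il6 at −1.34), type I interferon genes (31, median −0.11), mitochondrially encoded genes (13, median −0.75), dendritic markers (5, median −0.98) and smooth muscle markers (5, median −0.79), the last 4 at adjusted p = 0.0358. Without siCmpk2 library 4, camera called 3 lists: oxidative phosphorylation (median 1.45, adjusted p = 0.000335), smooth muscle, still lower (adjusted p = 0.044), and resident-like macrophage genes, higher (median 1.78 against 0.75 for all genes, adjusted p = 1.73e-11). NF-kB genes then turned from a median of −0.53 to 0.71 (adjusted p = 0.793) and mitochondrially encoded genes from −0.75 to 0.80 (adjusted p = 0.17), and neither was called. Without siControl library 3, 3 lists were called, and without siCmpk2 library 1, siCmpk2 library 2 or siControl library 5, 1 was. The other 19 lists tested were not called. These were interferon gamma, inflammasome, DNA sensing, pyrimidine synthesis, mitochondrial DNA maintenance, glycolysis, lipid-laden, LXR, cholesterol biosynthesis, resident-like, monocyte, iron recycling, efferocytosis, MHC class II, integrin, protease, cell cycle, dissociation stress and fibroblast genes, with adjusted p from 0.066 to 0.974. Several of them ranked below other genes with a median above 0 (interferon gamma, inflammasome, glycolysis, lipid-laden, MHC class II, integrin, protease and cell cycle genes), and the LXR and efferocytosis lists had a mean above 0 beside a median below 0. The endothelial, T, B, NK, mast, erythroid, adipocyte, neutrophil and platelet markers had under 5 tested members. The 1 tested T cell marker was higher when adjusted over the list alone.

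Whether genes that differ between the sorted populations also moved with the siRNA was asked across the 6240 genes tested in both experiments. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.0524 and Spearman rho = 0.0631. Other divisions of the siRNA libraries gave correlations of up to 0.187 in size. Of the 200 genes most clearly higher in VCAM1 positive libraries, 47 were tested in the siRNA experiment and did not rank apart from the others (camera adjusted p = 0.522). Of the 82 called lower, 14 were tested (adjusted p = 0.26). With an estimated correlation camera gave adjusted p = 0.849 for each set. Without siCmpk2 library 4, the lower set ranked lower in siCmpk2 libraries at the preset correlation (adjusted p = 0.00608), and an estimated correlation was not run there.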

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

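The tests of explanations in this part were chosen after the result was seen, except the one on arterial endothelial genes and the fit without siCmpk2 library 4, which was planned.

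A library far from the others of its group was found in 23 of 172 groups of values, where chance gives about 1 in 20, or 8.6. There were 7 in the VCAM1 experiment and 16 in the siRNA experiment. siControl library 3 stood above its group in reads (43.9 M against 1.15 to 4.25 M), in genes above 0 (16969) and in RPKM of S100a6 (9.56), Psmd6 (11.04), S100a11 (47.8) and Inpp5k (5.72). siCmpk2 library 4 stood below its group at 0 for Nlrp3, Il1b, Irf1, Adgre1, Cd68, S100a6, S100a11 and Uqcr10. Cd68 was low in siControl library 5 (33.7) and Cep83 in siControl library 4 (3.11). In the VCAM1 experiment, negative library 4 was low for Vcam1 (1.20), Selp (0.739) and Ace (5.89), and negative library 3 for Rgcc (7.58). Positive library 4 was high for Rgcc (11.5) and low for Pltp (48.1), and positive library 3 was high for Cd3d (1.23).

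Of resident-like macrophage genes 17 of 21 were called higher in VCAM1 positive libraries, and of T cell markers 8 of 11 lower. Of neutrophil markers 1 of 15 was, and their median turned to 0.10 without the negative libraries of aortas 4 to 6. T cells in the negative libraries of aortas 4 to 6 alone are argued against. Relative to all genes, their list lay at −1.23, −0.893 and −1.3 log2 units in aortas 1 to 3 too. The neutrophil list lay at −0.968, −0.409 and −0.596 there, and both lists together at −0.862. For neutrophils these values argue against that explanation too, though the list lay lower in aortas 4 to 6 (mean −2.62 against −0.658). The median that turned came from a fit that kept the positive libraries of aortas 4 to 6, so differences between the sets entered it. A lower share of macrophages in the negative libraries may carry the rise: the resident-like difference exceeded that of 6 general macrophage genes by a mean of 0.588, in 5 of 6 aortas (exact sign-flip p = 0.0938, two-sided). Those 6 genes differed among themselves, from a log2 fold change of 0.429 for Lyz2 to 1.86 for Adgre1, so the excess depends on the genes used. In aortas 1 to 3 the excess was 0.619, 0.327 and 0.917, beside differences of 0.37, 0.51 and −0.198 for the general macrophage genes. A lower share of macrophages alone is argued against there, as far as these 6 genes measure it. In aortas 4 to 6 the excess was −0.39, 0.989 and 1.07, beside 3.44, 2.18 and 1.73. A lower share of macrophages and a difference in macrophage state by VCAM-1 cannot be told apart there, because the spread is too wide. Of 100 divisions of the libraries, 1, the real one, gave 1408 genes (highest other 8), and of the 32 that part the aortas 1 gave 3629 (highest other 0), so chance can be excluded for the genes. It cannot be for the number of lists, where 53 of 100 divisions gave at least 12 (highest other 20) and 27 of 32 with the aorta as a block (12, highest other 19).

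Vascular genes (Cytl1, Clu, Selp, Smoc1 and Vwf) were higher in positive libraries in 6 of 6 aortas. A larger overall share of endothelial cells is argued against in aortas 4 to 6, where the median of the endothelial list, fixed without these genes' values, was lower in positive libraries (mean −0.519, below 0 in 3 of 3 aortas). It stays open in aortas 1 to 3, where that median was higher (mean 1.22). A larger share of smooth muscle cells is argued against in aortas 1 and 2, where the list's median was −1.17 and −0.694. In aorta 3 that median was 0.876 (mean of aortas 1 to 3, −0.331). The list's highest member rose by at most 1.92 in aortas 1 to 3. The vascular genes rose there by a median of at least 3.58, but they were picked for their rise. A larger share of smooth muscle cells stays open in aorta 3 and in aortas 4 to 6 (mean 1.82). Arterial endothelial cells that carry VCAM-1 could pass the positive gate: 10 arterial genes lay 0.602 above all genes, in 5 of 6 aortas, too variable to decide. A change in the macrophages themselves is also open. In the total plaque macrophages of the siRNA experiment Vwf was listed at 0 to 1.07 RPKM and Selp at 0 to 0.885. In the VCAM1 positive libraries they were listed at 15.5 to 202.6 and 3.04 to 49.8. Both genes were thus low in total plaque macrophages. VCAM-1 positive macrophages were not separated there and depth was uneven, so the comparison across experiments does not decide it.

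No gene was called between the siRNA groups, and Cmpk2 was not measured lower. With a real count of 0 genes, all 100 of 100 divisions gave as many, which says nothing about chance. The highest other gave 752, which points to a structure of the samples. That same division put the 5 libraries with the highest exonic share (4 siCmpk2 and siControl library 3, at least 38.8%) against the rest (at most 30.3%). It also holds 4 of the 5 deepest libraries and leaves siCmpk2 library 4 on the other side, so exonic share could be a cause but is not singled out. siCmpk2 library 4 itself, with few reads, also stays open: 21 genes were called without it, but 0 after centring. Whether Cmpk2 was lowered cannot be told, as the 95% interval reached −0.868, below the −0.52 that 0 in all 5 siCmpk2 libraries would give. For the 6 lists called at the preset correlation, 3 of 100 divisions, the real one included, gave as many. That share is under 0.05, but another division gave 7, so the count alone does not set the real groups apart. At that correlation 1 list was called without siCmpk2 library 1, siCmpk2 library 2 or siControl library 5, and with an estimated correlation 0 lists passed with all libraries.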

How the results depend on the processing

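Chosen after the data were seen were equal RPKM sums, centring with the block, the fits of aortas 1 to 3, of aortas 4 to 6 and without negative libraries 4 to 6, the centred fit without siCmpk2 library 4 and the fit above 4 M reads. The planned count-based alternatives were not run, because the tables hold no counts. Depth was uneven in the siRNA experiment, where 3 reads on Cmpk2 correspond to up to 19.7 RPKM. Vcam1 kept its direction and its call in every alternative run, at adjusted p of 2.2e-06 to 0.0379.

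In the VCAM1 comparison the 1408 genes became 598 with quantile normalization, 551 with centring, 4605 with array weights, 433 at a mean RPKM of at least 5 (fewer genes tested), 127 at adjusted p under 0.01, 432 with a log2 fold change of at least 1, 3629 with the aorta as a block, 102 in aortas 1 to 3 (970 with the block), 1433 in aortas 4 to 6 (3733 with the block) and 132 without negative libraries 4 to 6. Leaving out each library gave 558 to 3004. With the block, the 47 called named genes were called, and so were Tmem173, Adgre1 and Cd68, with 12 lists as before. Lists called fell from 12 to 0 with an estimated correlation and to 0 with fry. Cmpk2 passed at −0.64 with quantile normalization, −0.64 with centring, −0.64 with centring and the block, and −0.51 with equal sums. The direction reversed for genes not called with all libraries: Nlrp3 −0.14 in aortas 1 to 3, with and without the block. Il1b was −0.14 with quantile normalization, −0.12 with centring with or without the block, −0.91 in aortas 1 to 3 with or without it (called with it, adjusted p = 0.0157), and −0.59 without negative libraries 4 to 6. Cgas was 0.0289 at a pseudocount of 0.1 and 0.0484 in aortas 4 to 6 with or without the block. Irf1 was −0.26 with quantile normalization, −0.20 with centring with or without the block, −0.10 with equal sums and −0.0104 in aortas 1 to 3 with or without it. Leaving out libraries gave ranges of −0.31 to 0.78 for Il1b, −0.13 to 0.15 for Cgas and −0.018 to 0.20 for Irf1. The cause was not tested.

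In the siRNA comparison the 0 genes became 103 with array weights and 1 above 4 M reads, and 0 to 21 on leaving out each library. The replicate number as a block called 0 genes (245 at an unadjusted p under 0.05). Deviations of same-numbered libraries correlated at −0.00807, −0.0211, 0.079, 0.0234 and −0.0644, and 1 of 5 matched its own number best. Lists called fell from 6 to 0 with an estimated correlation, 0 with fry and 3 above 4 M reads (1 to 7 on leaving out libraries). The Cmpk2 difference was −0.0209 with centring and −0.10 to 0.47 on leaving out libraries. The direction reversed for uncalled genes. With equal sums Itga4 was −0.29, Tmem173 −0.32, Cgas −0.30 and Irf1 −0.47. Cgas was −0.15 with quantile normalization, −0.12 with centring and −0.28 when centred without siCmpk2 library 4. Irf1 was −0.22 at a pseudocount of 0.1. With array weights Nlrp3 was 0.20, Adgre1 0.90 and Cd68 1.39. Cd68 was 0.53 when centred without siCmpk2 library 4. Above 4 M reads Adgre1 was 1.14, Cd68 2.05 and Parp3 0.47. Leaving out libraries gave −0.0184 to 1.05 for Itga4, −0.78 to 0.62 for Nlrp3, −1.90 to 0.0401 for Il1b, −0.23 to 0.91 for Tmem173, −0.20 to 0.69 for Cgas, −0.0189 to 1.39 for Irf1, −0.89 to 0.70 for Adgre1 and −0.76 to 1.40 for Cd68. The cause was not tested.

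Of the other values of single genes and lists, 776 kept their direction and side of the threshold under the alternatives, 18 passed it, 262 no longer did and 32 reversed. On leaving out libraries the counts were 649, 7, 170 and 22.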

Other observations

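The genes in this part, the general macrophage list and the correlation across experiments against other divisions were chosen or tested after the results were seen. The test of the arterial list was written before its result.

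Among 10 genes of arterial endothelium, 5 were called higher in VCAM1 positive libraries and 0 lower. They were the kinase Bmx (2.06, limma adjusted p = 0.0121), the adhesion receptor Sele (2.09, adjusted p = 0.0187), the gap junction gene Gja4 (1.93, adjusted p = 0.0207), the matrix gene Fbln5 (1.85, adjusted p = 0.0059) and the peptide gene Edn1 (1.80, adjusted p = 0.034). Dll4 (−0.81, adjusted p = 0.173), Hey1 (−0.88, adjusted p = 0.133) and Sema3g (−0.323, adjusted p = 0.645) lay the other way and were not called. Bmx was listed at 24.2, 14.9 and 9.92 RPKM in positive libraries 1 to 3 and at 2.36, 4.63 and 5.13 in positive libraries 4 to 6, against 0.475 to 1.94 in the negative libraries. Arterial endothelial cells may add to the positive libraries, but the list as a whole lay 0.602 above all genes with no decision. The sort was for macrophages, yet the endothelial gene Cdh5 was listed at 24.3 to 133.4 RPKM in positive and 12.4 to 91.9 in negative libraries. The smooth muscle gene Myh11 was listed at 24.2 to 240.7 in positive and 18.4 to 262.1 in negative libraries. The erythroid gene Hba-a2 was at 90.1 to 786.7 and 213 to 3810. In negative libraries 1 and 2 Myh11 (262.1 and 198.9) exceeded the macrophage gene Csf1r (62.7 and 56.0).

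Without siCmpk2 library 4, 21 genes were called higher in the libraries labelled siCmpk2 and 0 lower. The median of all tested genes was itself 0.75 in that fit, and 0 genes were called when the libraries were also centred. The 21 genes included the chemokines Ccl6 (2.47, adjusted p = 0.0375), Ccl8 (2.71, adjusted p = 0.0409) and Ccl9 (2.38, adjusted p = 0.0409), complement C1qc (1.92, adjusted p = 0.0409) and the respiratory chain gene Ndufa2 (2.68, adjusted p = 0.0454). C1qc was listed at 530, 820, 1140 and 1600 RPKM in these siCmpk2 libraries and at 362, 290, 321, 178 and 158 in the siControl libraries. Retnla was listed at 159, 247, 300, 0 and 372 in the siCmpk2 libraries and at 11.9, 175, 11.7, 81.3 and 2.36 in the siControl libraries.

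The correlation of log2 fold changes between the experiments, 0.0524, was reached by 72 of 100 divisions of the siRNA libraries (highest other 0.187), so chance cannot be excluded.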
